A study of Mus musculus with 24 samples.

How the data were processed

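Kidney RNA of 24 male ICR mice was measured on Agilent single-colour arrays, 1 array per sample, in groups taken from the labels: sham (n = 6), alloxan-diabetic (DKD, n = 9) and alloxan-diabetic with enarodustat in feed (n = 9). Per the labels, total RNA was isolated on columns, quantified by absorbance, checked on a Bioanalyzer and labelled with Cy3 by a low-input protocol. The series text describes each group by its number of mice, so the replicates were taken as separate mice, with diabetic groups matched on blood glucose and body weight. The replicate numbers name samples only.

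Each scanner file holds 1 array, whose spot signals are intensity values per the file headers, background subtracted and detrended within the array by Agilent Feature Extraction 12.1.1.1 and not scaled between arrays. The submitters' processing notes name version 11.5.1.1 and limma, with no role or order, and how the submitters used them is not given in the sources used here. The deposited values cover 31409 probes, all well above background on every array, where 31435 probes are. Their log2 scale, unstated by the authors, was found by comparison with the scanner files: normexp background correction with an offset of 50 on the median spot signals, then quantile normalization, gave all but 299 of 753816 deposited values within a tolerance of 0.05 (median absolute difference 0.0086, largest 0.106). The columns have medians of 7.543 to 7.559 and are not centred per gene, and nothing about their scale, centring or direction stayed open.

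The array design (074809) has 59305 non-control and 3671 control spots. Control spots were left out, spots of 1 probe were averaged, and 20 values of tested genes with an outlier mark were dropped. Gene names came from the probes' accessions through a RefSeq table of assembly GRCm38.p6, without versions: 32994 of 56605 probes were named and 23611 were not, and the names cover 22911 symbols. No coordinates are given, since the array grid names another build. The probe with the highest mean signal over all arrays stood for its gene, and a gene was tested if that probe was well above background on at least 6 of 24 arrays, which left 17736 genes. Where probes of a named gene changed in different directions, this is said beside the value.

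The main values are log2 of the processed signal minus the 75th percentile of the array, which lay at signals of 187 to 388. Spots well above background numbered 37716 to 44732 per array, a median of 68.6% of the non-control spots, and 0 non-control spots were saturated. The scanner software gave 1 array, enarodustat 3, a quality warning, and it was kept. The arrays fill 3 slides of 8, each with 2 sham, 3 DKD and 3 enarodustat arrays, and each slide was scanned as 1 set. Deviations from the group means correlated at a median of 0.189 for arrays of different groups on 1 slide and at −0.093 on different slides, and the consensus correlation within slides was 0.076. Sham arrays lay in row 1 of a slide and enarodustat arrays in row 2, with 6 DKD arrays in row 1 and 3 in row 2. Columns also followed the group.

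All 24 arrays entered 1 limma fit (R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table) with group as the only term, from which the contrasts DKD minus sham, enarodustat minus DKD and enarodustat minus sham were taken. P-values are two-sided, from moderated statistics, and were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. A gene not well above background on any array of a group has only a bound there: the mean of the brighter group was divided by the mean, over the arrays of the dimmer group, of the higher of the lowest signal well above background and the probe's own signal, and the fold is given as "at least". SE is that of the limma contrast, SD is across arrays, and the number of arrays limits the precision.

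For 46 gene lists (pathways, responses and cell type markers) with at least 5 tested members, camera of limma with its preset correlation of 0.01 compared the members with all other genes, with adjustment over the 46 lists of a comparison. Camera with an estimated correlation, fry, which tests whether members move on balance 1 way without comparing them with other genes, and an exact permutation test of the list mean per array stand beside it. The list mean is the mean over members of each array's difference from the sham mean, and values within slides are medians over members. Members were counted with p adjusted over all genes and adjusted over the list alone.

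The genes named were the 8 with the largest rise and the 8 with the largest fall among those that passed, had a gene name and were well above background on at least 50% of the arrays of both groups. Further named were up to 4 passing members of each called list with the largest change, a fixed set of genes given with values in every comparison, up to 4 genes per direction bounded by background, and the 10 opposite-direction genes with the largest smaller change. Some genes chosen by this rule are not reported here. Names outside the rule are marked as singled out after their values were seen. The lists, this rule, the fits, the threshold and the alternatives were fixed before the data were examined, except for alternatives chosen after seeing the data: normexp on the median signals, the comparisons within 1 slide row, slide row as a term in the fit, and the exact permutation test of list means.

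Genes that passed in DKD against sham and in enarodustat against DKD share the DKD arrays with opposite signs. The overlap was therefore set beside that of independent lists and of 100 simulated draws of unchanged groups, and recomputed with odd-numbered DKD arrays in one comparison and even-numbered ones in the other, in both arrangements. Gene and list tests were run on simulated data of the 17736 genes, each drawn independently of the others. In DKD against sham, 36.5%, 72.7% and 94.4% of genes changed by 1.5, 2 and 3-fold were recovered. For enarodustat against DKD the shares were 56.0%, 80.3% and 95.3%, and for enarodustat against sham 45.7%, 83.3% and 89.1%, with 8, 10 and 7 false calls of 146, 162 and 151. A list shifted by 0.5 was called in each comparison, with 0 other lists. Alternatives covered the background correction, 4 other scalings or tables, the filter on dim probes, the probe rule, slide as a fixed or random block, slide row as a term, the replicate number as a block, the groups in the fit, array weights, the variance prior, the threshold, and each array left out in turn.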

Results

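RNA of whole kidneys from male ICR mice was measured on 24 single-colour arrays, 1 per mouse. The groups were sham mice (n = 6), mice made diabetic with alloxan, called DKD for diabetic kidney disease (n = 9), and diabetic mice given enarodustat in feed, called the enarodustat group (n = 9). Enarodustat inhibits the prolyl hydroxylases that mark hypoxia-inducible factor (HIF) for degradation. Alloxan, which destroys insulin-producing cells, was given at 90 mg/kg 3 days before grouping, the drug made up 0.01% of the feed, and kidneys were taken 16 days after grouping. Each of the 3 slides held 2 sham, 3 DKD and 3 enarodustat arrays. Sham arrays lay in the first row of a slide and enarodustat arrays in the second, with 6 DKD arrays in the first and 3 in the second. Across genes, arrays of 1 group correlated at 0.964 to 0.991, and their number limits the precision of every value. Levels are log2 signals relative to the 75th percentile of the array, changes are log2 differences ± SE from limma, and a gene or list is said to rise or fall where its adjusted p passed 0.05.

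DKD was set against sham to show which RNAs differ in the diabetic kidney. Grem1, a secreted antagonist of bone morphogenetic proteins, rose by 3.65 ± 0.34 (adjusted p = 2.35e-06), from −4.13 ± 0.55 (SD, n = 6) to −0.48 ± 0.80 (SD, n = 9). Kynu, which degrades tryptophan metabolites, rose by 3.73 ± 0.55 (adjusted p = 0.000139), and Bhmt, which remethylates homocysteine, by 2.95 ± 0.47 (adjusted p = 0.000263). Gsta2, a glutathione transferase, rose by 2.59 ± 0.51 (adjusted p = 0.00171), and the fatty acid omega-hydroxylases Cyp4a14 and Cyp4a10 rose by 2.75 ± 0.87 (adjusted p = 0.041) and 2.22 ± 0.45 (adjusted p = 0.00207). Synpr, a vesicle membrane protein, had the largest fall, −7.02 ± 1.42 (adjusted p = 0.00205), with the probe well above background on 5 of 9 DKD arrays. The annexin Anxa13 fell by 3.25 ± 0.45 (adjusted p = 8.37e-05), and the xenobiotic cytochromes Cyp2b10 and Cyp2b9 fell by 3.13 ± 0.60 and 3.08 ± 0.60 (adjusted p = 0.00143 and 0.00142). Ctxn3, the alcohol dehydrogenase Adh6a, the secreted protein Angptl7 and Srd5a2, which makes dihydrotestosterone, changed by −3.08, −2.93, −2.90 and −2.74 (adjusted p = 0.00776, 0.000892, 5.76e-05 and 0.000119). Slc34a2, a phosphate transporter, was not well above background on any sham array and was at least 1.57-fold higher in DKD (adjusted p = 0.00192). Within slides 1, 2 and 3 the changes were 3.68, 3.05 and 4.22 for Grem1, −8.22, −4.37 and −8.47 for Synpr, and 4.28, 0.34 and 3.62 for Cyp4a14. Cyp4a14 no longer passed without sham 1, 2, 3, 4, 5 or 6 or DKD 2, 3, 7 or 9 (adjusted p up to 0.0956), or with background correction by normexp on the median signals (1.11, adjusted p = 0.131), which also ended the call of Slc34a2 (0.038, adjusted p = 0.877). Kynu, Grem1, Synpr, Cyp2b10, Cyp2b9, Ctxn3, Adh6a and Srd5a2 changed by 1.615, 1.74, −3.88, −1.86, −1.40, −1.355, −0.83 and −1.36 after normexp on the median signals, still passing.

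Among genes of energy metabolism, targets of the fatty acid receptor PPAR alpha with ketogenesis genes rose as a list. Of 23 tested, 12 rose, 2 fell and 9 did not pass (15 and 3 adjusted over the list alone). The PPAR alpha mean was 0.96 in 9 of 9 DKD arrays (SD 0.54 against 0.21 in sham; adjusted p = 9.18e-06, and adjusted p = 0.356 with an estimated correlation). Creb3l3, a transcription factor of lipid metabolism, rose by 2.44 ± 0.60 (adjusted p = 0.00916) beside Cyp4a14 and Cyp4a10. The 2 that fell, singled out after their values were seen, were the fatty acid transporter Cd36 (−1.17) and the ketone body dehydrogenase Bdh1 (−0.95). Of 20 glycolysis genes, 6 rose and 14 did not pass (8 rose adjusted over the list alone). The glycolysis mean was 0.17 in 8 of 9 arrays (adjusted p = 0.0113, and adjusted p = 0.600 with an estimated correlation). Aldoc rose by 1.00 ± 0.14, Eno2 by 0.55, Pklr by 0.52 and Pkm by 0.49. Mitochondrial fatty acid oxidation genes gave 6 risers and 16 that did not pass of 22 (7 and 3 fallers adjusted over the list alone). The fatty acid oxidation mean was 0.20 in 7 of 9 arrays (adjusted p = 0.0167, and adjusted p = 0.632 with an estimated correlation; adjusted exact p = 0.151). Its leading members Acaa2, Cpt1b, Acsl1 and Eci1 rose by 1.25, 0.69, 0.61 and 0.58. Cholesterol synthesis fell, with 11 fallers and 11 that did not pass of 22 (14 fallers adjusted over the list alone). The cholesterol synthesis mean was −0.49 in 9 of 9 arrays (adjusted p = 2.95e-08, and adjusted p = 0.139 with an estimated correlation). Idi1 changed by −1.42. Branched-chain amino acid degradation had a mean of −0.16 in 7 of 9 arrays (adjusted p = 0.0265, and adjusted p = 0.693 with an estimated correlation; adjusted exact p = 0.242). Of its 20 genes Ivd (−0.74) and Mccc1 (−0.65) fell, also 2 adjusted over the list alone. List medians within slides 1, 2 and 3 were 0.90, 0.34 and 0.81 for PPAR alpha and ketogenesis, 0.23, 0.08 and 0.19 for glycolysis, 0.27, 0.02 and 0.13 for fatty acid oxidation, −0.45, −0.39 and −0.42 for cholesterol synthesis, and −0.09, −0.20 and −0.17 for branched-chain degradation. The fatty acid oxidation list no longer passed without sham 6 or DKD 3 (adjusted p up to 0.0581). Branched-chain degradation lost its call without sham 2, DKD 5 or DKD 8 (adjusted p up to 0.099). Eno2 lost its call when any 1 of 19 arrays was left out (all but DKD 4 and 8 and enarodustat 1, 5 and 9; adjusted p up to 0.104). Pklr lost it when any 1 of 15 was (all but sham 4, DKD 1 and 5 and enarodustat 4, 5, 6, 7, 8 and 9; adjusted p up to 0.105). Eci1 lost its call without sham 1, 3, 5 or 6 or DKD 2, 3, 6, 7 or 9 (up to 0.0833). Acsl1 lost its call without sham 3 or 4 or DKD 2 (up to 0.0741). Normexp on the median signals ended the calls of Creb3l3 (0.55, adjusted p = 0.171), Eno2 (0.15, adjusted p = 0.428) and Pklr (0.27, adjusted p = 0.154).

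Several energy lists were not called in DKD. Of 63 nuclear genes of oxidative phosphorylation, 0 rose and 0 fell (list mean −0.08, adjusted p = 0.199), and the 18 genes of the TCA cycle likewise gave 0 and 0 (mean 0.01, adjusted p = 0.714). In pyruvate oxidation (mean 0.19, adjusted p = 0.606) 1 of 12 genes changed, the pyruvate dehydrogenase kinase Pdk4, which rose by 1.66 ± 0.34 (adjusted p = 0.0023). Gluconeogenesis and fructose metabolism had a mean of 0.09 (adjusted p = 0.714) and 4 changed genes of 12. Pck1, the gatekeeping enzyme of gluconeogenesis, rose by 0.79 ± 0.16 (adjusted p = 0.00254). The others, singled out after their values were seen, were Fbp2 (1.53), Akr1b3 (−0.69) and Pcx (−0.44). HIF target genes had a mean of 0.19 (adjusted p = 0.111; adjusted exact p = 0.0352), with 7 risers, 1 faller and 30 that did not pass. The HIF prolyl hydroxylase Egln3 was among the risers, at 1.02 ± 0.23 (adjusted p = 0.00489), and Egln1 was the faller (−0.22, singled out after its value was seen). Lipogenesis had 2 risers and 7 fallers of 21 (mean −0.18, adjusted p = 0.0656; adjusted exact p = 0.0318), the risers being Acacb (0.64) and Elovl6 (0.87), singled out after their values were seen. Txnip, which responds to glucose, rose by 0.70 ± 0.17 (adjusted p = 0.00802). Differences that did not pass were 0.85 for Pdk1 (adjusted p = 0.156), 0.19 for Vegfa (adjusted p = 0.349), 0.08 for Cpt1a, 0.08 for Slc2a1, 0.03 for G6pc, −0.03 for Pfkp, −0.11 for Ldha and −0.36 for Acadm (adjusted p = 0.0611). Hk2 differed by −0.61 (adjusted p = 0.322), and its probe was well above background on 3 of 9 DKD and 4 of 6 sham arrays. The signs of G6pc, Pfkp and Ldha turned under some other settings, and probes of Pdk1 and Vegfa differed in sign. Egln3 changed by 0.56 after normexp on the median signals, still passing. Epo was not tested, since it was well above background on 0 sham, 1 DKD and 1 enarodustat array.

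Cell proliferation genes rose in DKD, with 15 risers and 16 that did not pass of 31 (24 risers adjusted over the list alone). The proliferation mean was 0.75 in 8 of 9 arrays (SD 0.53 against 0.07 in sham; adjusted p = 5.66e-13, and adjusted p = 0.356 with an estimated correlation). The mitotic regulators Cdc20 and Aurka and the nucleotide reductase subunit Rrm2 rose by 1.26, 1.08 and 1.16, and Bub1, above background on no sham and on 8 of 9 DKD arrays, was at least 1.74-fold higher (adjusted p = 0.034). Kidney genes with higher expression in males fell, with 12 fallers and 5 that did not pass of 17 (14 fallers adjusted over the list alone). The male-biased mean was −1.03 in 9 of 9 arrays (SD 0.44 against 0.15; adjusted p = 1.53e-11, and adjusted p = 0.139 with an estimated correlation). Gusb, Cyp4a12a, Cyp4a12b and Slco1a1 changed by −2.71, −1.68, −1.64 and −1.61. Genes of the unfolded protein and integrated stress responses gave 13 fallers and 11 that did not pass of 24 (15 fallers adjusted over the list alone). The unfolded protein mean was −0.38 in 9 of 9 arrays (adjusted p = 1.59e-08, and adjusted p = 0.130 with an estimated correlation). Sdf2l1, Chac1, Sel1l and Creld2 changed by −0.82, −0.79, −0.71 and −0.66. Tubular injury genes gave 6 risers, 1 faller and 19 that did not pass of 26 (10 and 1 adjusted over the list alone). The tubular injury mean was 0.48 in 9 of 9 arrays (adjusted p = 0.000311, and adjusted p = 0.358 with an estimated correlation). Spp1, Gdf15 and Krt18 rose by 1.15, 0.90 and 0.85, Cdkn1a by 1.52 at one probe with −0.02 at the other, and the faller was Tnfrsf12a (−0.67, singled out after its value was seen). The injury markers Lcn2 and Havcr1 differed by 0.84 (adjusted p = 0.0761) and 0.13 without passing, the latter with a sign that turned under some other settings. Interferon response genes had a mean of 0.18 in 7 of 9 arrays (adjusted p = 0.0294, and adjusted p = 0.632 with an estimated correlation; adjusted exact p = 0.291). Ifit2 (0.55) and Ddx58 (0.44) rose and 20 did not pass, also 2 risers adjusted over the list alone. Medians within slides 1, 2 and 3 were 0.51, 0.90 and 1.09 for proliferation, −1.01, −0.84 and −1.19 for male-biased genes, −0.49, −0.38 and −0.45 for the unfolded protein response, 0.62, 0.23 and 0.27 for injury, and 0.13, 0.19 and 0.19 for interferon. The interferon list lost its call without sham 2 or 5 or DKD 3, 4 or 6 (adjusted p up to 0.307). Bub1 lost its call without sham 1, 2 or 4 or DKD 2, 4, 5, 7 or 9 (up to 0.107). Chac1 lost its call without sham 1 or 3 (up to 0.0605). After normexp on the median signals Bub1 (0.082, adjusted p = 0.742) and Chac1 (−0.39, adjusted p = 0.0617) did not pass. Aurka, Cdkn1a and Ifit2 changed by 0.69, 0.97 and 0.22 after normexp on the median signals, still passing.

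Markers of several cell types differed beside these groups. Collecting duct principal cell markers rose, with 8 risers and 3 that did not pass of 11 (9 risers adjusted over the list alone). The principal cell mean was 0.52 in 9 of 9 arrays (adjusted p = 1.86e-07, and adjusted p = 0.139 with an estimated correlation). The water channels Aqp4 and Aqp2, the transcription factor Elf5 and the vasopressin receptor Avpr2 rose by 1.19, 0.91, 0.85 and 0.57. Lymphocyte markers fell, with 6 fallers and 10 that did not pass of 16 (12 fallers adjusted over the list alone). The lymphocyte mean was −0.83 in 9 of 9 arrays (adjusted p = 4.53e-08, and adjusted p = 0.130 with an estimated correlation). Jchain, Klrb1c and Gzma changed by −1.79, −1.68 and −1.26, and Gzmb, above background on no DKD array, was at least 1.43-fold lower (adjusted p = 0.00177). Podocyte markers had a mean of 0.26 in 9 of 9 arrays (adjusted p = 0.00867, and adjusted p = 0.358 with an estimated correlation). Cdkn1c rose (0.95), Npr3 fell (−0.51) and 12 did not pass, also 1 and 1 adjusted over the list alone. Erythroid markers had a mean of −0.54 in 8 of 9 arrays (SD 0.38; adjusted p = 0.0402, and adjusted p = 0.573 with an estimated correlation). The globins Hbb-bt, Hba-a1 and Hba-a2 fell by 0.95, 0.94 and 0.93 and 7 markers did not pass (1 riser and 5 fallers adjusted over the list alone). Proximal tubule markers (mean −0.02, adjusted p = 0.741; 6 risers, 8 fallers and 19 that did not pass), macrophage markers (−0.13, adjusted p = 0.196) and endothelial markers (0.10, adjusted p = 0.0838) were not called, nor were fibrosis genes (0.01, adjusted p = 0.878). Medians within slides 1, 2 and 3 were 0.65, 0.39 and 0.34 for principal cells, −0.48, −0.92 and −0.41 for lymphocytes, 0.21, 0.20 and 0.27 for podocytes, and −0.16, −1.08 and −1.20 for erythroid cells. The erythroid list lost its call without sham 2, 3 or 4 or DKD 3, 4, 6, 8 or 9 (adjusted p up to 0.0934). Hbb-bt lost its call without sham 2, 3, 4 or 5 or DKD 6, 7, 8 or 9 (up to 0.0873). Hba-a1 and Hba-a2 lost their calls without sham 2, 3, 4 or 5 or DKD 8 (up to 0.0861 and 0.0873). Aqp4 was lost without sham 1, 2 or 4 (up to 0.0882). Jchain lost its call without sham 1, 3 or 4 (up to 0.0745). Gzmb lost its call after normexp on the median signals (−0.15, adjusted p = 0.382). Elf5, Klrb1c and Gzma changed by 0.28, −0.41 and −0.81 after normexp on the median signals, still passing.

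In all, 2058 of 17736 genes passed between DKD and sham, 971 higher and 1087 lower, with a median absolute change of 0.57, and 993 differed at least 1.5-fold. With slide as a fixed block 2447 genes passed, and within slides 1, 2 and 3 alone 15, 0 and 9 did by limma (2202, 1656 and 1616 at an unadjusted p under 0.05). All 76 genes of the naming rule that passed kept their sign in the 3 slides, and for 69 of them every DKD array lay on the called side of the sham mean. Of 46 lists 14 were called, 14 with slide as a fixed block and 0 with an estimated correlation. Fry called 14 (5 calls lost) and exact permutation 17 (3 lost). The share of higher calls, 47.2%, was 34.7% after normexp on the median signals. DKD and sham arrays of the first slide row alone gave 1956 genes and 12 lists. With slide row as a term in the fit of all arrays, 2182 genes and 12 lists passed. This term ended 11 calls of the naming rule, with change and adjusted p in brackets, those of Cyp4a14 (2.47; 0.0965), Acsl1 (0.45; 0.111), Eci1 (0.41; 0.151), Eno2 (0.51; 0.0988), Pklr (0.39; 0.153), Aqp4 (1.02; 0.0875) and Avpr2 (0.45; 0.062). Hba-a1 (−0.75; 0.0985), Hba-a2 (−0.735; 0.101), Hbb-bt (−0.79; 0.104) and Jchain (−1.555; 0.0714) were the others. The erythroid, interferon and fatty acid oxidation lists were not called either (adjusted p = 0.198, 0.115 and 0.205).

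**Figure D1:**
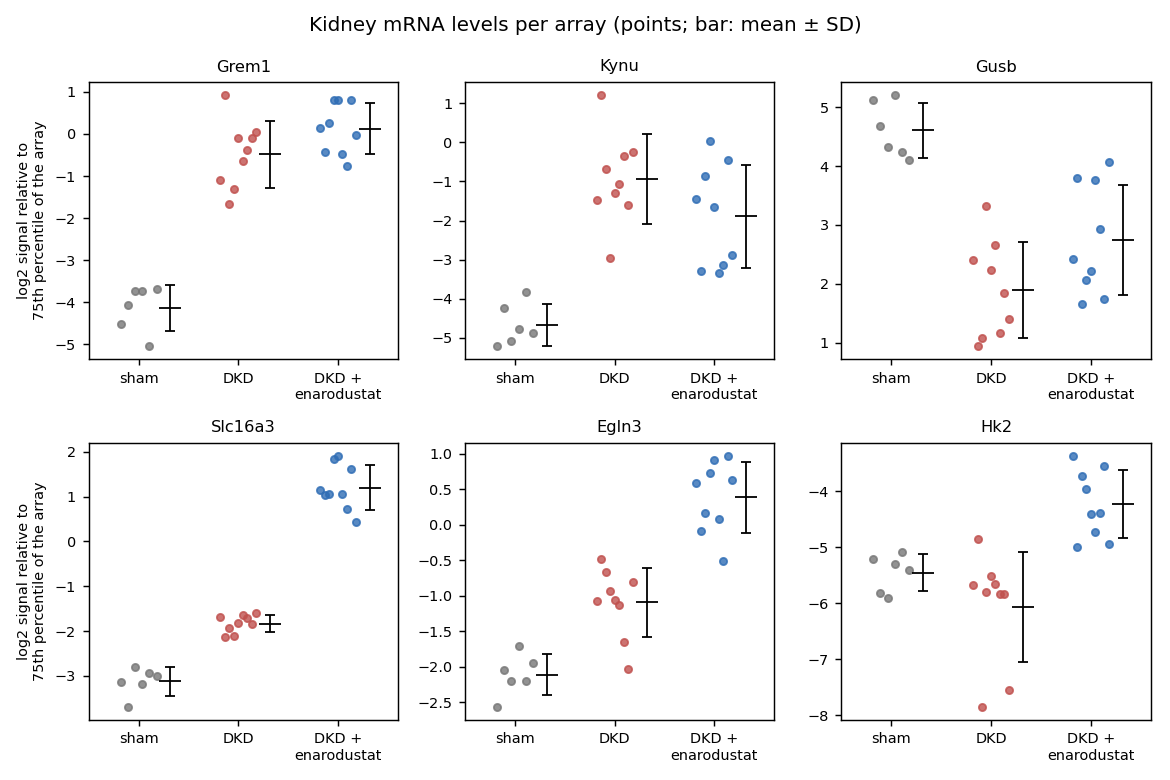
Log2 signal relative to the 75th percentile of the array for Grem1, Kynu, Gusb, Slc16a3, Egln3 and Hk2 in sham (6 arrays), DKD (9) and enarodustat (9) kidneys; points are arrays and bars are the mean ± SD. Slc16a3 lay at −1.83 ± 0.20 in DKD and at 1.20 ± 0.50 with enarodustat, while Grem1 rose from −4.13 ± 0.55 in sham to −0.48 ± 0.80 in DKD.

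The enarodustat group was set against DKD to show the effect of the drug in diabetic kidneys. Slc16a3, which exports lactate from cells, rose by 3.03 ± 0.17 (adjusted p = 4.27e-11), 8.19-fold, from −1.83 ± 0.20 (SD, n = 9) to 1.20 ± 0.50 (SD, n = 9). Mgarp, a mitochondrial protein, rose by 3.47 ± 0.35 (adjusted p = 2.76e-06), 11.1-fold, and Ankrd37, a known HIF target, by 2.05 ± 0.17 (adjusted p = 7.25e-08). Tnfsf9, the ligand of the receptor 4-1BB, rose by 1.99 ± 0.16 (adjusted p = 7.25e-08). Prnd rose by 1.54 ± 0.28 (adjusted p = 0.00548) and Egln3 by 1.48 ± 0.21 (adjusted p = 0.000244). Rgs11, a regulator of G protein signalling, rose by 1.34 ± 0.15 (adjusted p = 1.05e-05) and the secreted stanniocalcin Stc1 by 1.20 ± 0.23 (adjusted p = 0.0095). The falls were smaller. Utp20, needed for ribosome assembly, changed by −0.65 ± 0.14 (adjusted p = 0.027), the protease Prss12 by −0.64 ± 0.10 (adjusted p = 0.00126), Klk1b27 by −0.57 (adjusted p = 0.0319) and the syntrophin Sntb2 by −0.55 ± 0.09 (adjusted p = 0.00188). The GTPase Rab6b, Zfp697, the calcium-sensing receptor Casr and Baiap2 changed by −0.48, −0.47, −0.46 and −0.42 (adjusted p = 0.024, 0.0401, 0.00493 and 0.0319). Within slides 1, 2 and 3 the changes were 2.99, 3.46 and 2.65 for Slc16a3, 3.88, 3.81 and 2.72 for Mgarp, and 0.96, 1.61 and 1.86 for Egln3. Without 1 array, Zfp697 lost its call for 17 of the 24 arrays (all but sham 2, 3, 5 and 6, DKD 7 and 9 and enarodustat 7; adjusted p up to 0.0796). Baiap2 lost it without DKD 2, 3, 5, 7 or 9 or enarodustat 3, 5, 6 or 8 (up to 0.0683). Klk1b27 lost its call without DKD 3, 5, 7 or 9 or enarodustat 4, 6, 7 or 8 (up to 0.0683). Utp20 lost its call without DKD 2, 3 or 7 or enarodustat 5 (up to 0.0573). Normexp on the median signals ended the calls of Prnd (adjusted p = 0.0902), Klk1b27 (adjusted p = 0.231) and Zfp697 (adjusted p = 0.0638). Among the 3 DKD and 9 enarodustat arrays in the second row of their slide, Mgarp, Slc16a3, Ankrd37, Tnfsf9 and Rgs11 still rose, by 2.95, 2.93, 1.92, 2.00 and 1.67 (adjusted p = 0.0189, 0.00276, 0.0143, 0.0139 and 0.0131), while Egln3, at 1.25, did not pass (adjusted p = 0.266). Of the 36 calls of the naming rule 29 were lost among these arrays. Mgarp, Tnfsf9, Stc1 and Prss12 changed by 1.503, 0.61, 0.47 and −0.34 after normexp on the median signals, still passing.

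HIF target genes and glycolysis rose with enarodustat, and both calls held with an estimated correlation. Of 38 HIF targets other than glycolytic enzymes, 13 rose and 25 did not pass (23 risers adjusted over the list alone). Their mean went from 0.19 ± 0.11 (SD, n = 9) in DKD to 0.65 ± 0.15 (SD, n = 9), a difference of 0.46 in 9 of 9 arrays. The list test gave adjusted p = 1.91e-23, and adjusted p = 0.000546 with an estimated correlation (adjusted exact p = 0.000946). Slc16a3, Ankrd37, Egln3 and Ddit4, an inhibitor of mTOR signalling, led the list at 3.03, 2.05, 1.48 and 1.01. Of 20 glycolysis genes, 10 rose and 10 did not pass (13 risers and 1 faller adjusted over the list alone). The glycolysis mean was 0.47 in 9 of 9 arrays (adjusted p = 1.04e-16, and adjusted p = 0.0198 with an estimated correlation; adjusted exact p = 0.000946). The phosphofructokinase genes Pfkl and Pfkp rose by 1.17 ± 0.10 (adjusted p = 2.72e-07) and 1.13 ± 0.14 (adjusted p = 7.43e-05) and Aldoc by 0.97 ± 0.12 (adjusted p = 7.05e-05). The hexokinase Hk2 rose by 1.84 ± 0.33 (adjusted p = 0.00525), with its probe well above background on 9 of 9 enarodustat and 3 of 9 DKD arrays. After normexp on the median signals, which shrinks dim genes, Hk2 differed by 0.22 (adjusted p = 0.214). Medians within slides 1, 2 and 3 were 0.29, 0.35 and 0.39 for HIF targets and 0.29, 0.61 and 0.42 for glycolysis. Ddit4 lost its call without DKD 3, 4, 5 or 7 or enarodustat 1, 2, 3 or 4 (adjusted p up to 0.0654). Among the arrays in the second row of the slides Pfkl and Pfkp rose by 1.29 and 1.31 (adjusted p = 0.0165 and 0.025), while Hk2 and Aldoc, at 2.79 and 0.84, did not pass (adjusted p = 0.0576 and 0.223). Pdk1 (1.02, adjusted p = 0.206), Ldha (0.47, adjusted p = 0.0643), Slc2a1 (0.42, adjusted p = 0.137) and Vegfa (0.40, adjusted p = 0.0892) did not pass in the comparison of the groups.

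Other parts of energy metabolism differed little between enarodustat and DKD. Mitochondrial fatty acid oxidation (mean −0.09 in 5 of 9 arrays) and the TCA cycle (−0.06 in 7 of 9) were called lower with 0 of 22 and 0 of 18 genes past the test, also 0 adjusted over the list alone. The list tests gave adjusted p = 0.00976 and 0.0332, and adjusted p = 0.638 and 0.681 with an estimated correlation (adjusted exact p = 0.721 and 0.820). Within slides 1, 2 and 3 their medians were −0.25, 0.07 and −0.09, and −0.16, 0.03 and −0.04, so that 1 slide had the opposite sign for each. Degradation of other amino acids was called lower at −0.12 in 6 of 9 arrays, with medians of −0.25, −0.01 and 0.01 within the slides (adjusted p = 0.00204, and adjusted p = 0.610 with an estimated correlation; adjusted exact p = 0.616). Its 1 member past the test went the other way: Acmsd, an enzyme of the kynurenine pathway, rose by 0.78 ± 0.15 (adjusted p = 0.0103), beside 1 riser and 2 fallers adjusted over the list alone. PPAR alpha targets and ketogenesis (mean −0.18, adjusted p = 0.120), oxidative phosphorylation (−0.02, adjusted p = 0.311), pyruvate oxidation (−0.05, adjusted p = 0.794), gluconeogenesis (−0.09, adjusted p = 0.150) and branched-chain amino acid degradation (−0.03, adjusted p = 0.189) were not called, with 0 members past the test in each. Nor was cholesterol synthesis, whose mean was 0.03 and median −0.02 (adjusted p = 0.744), or lipogenesis, whose test pointed down at a mean of 0.03 (adjusted p = 0.914). The other differences that did not pass were −0.51 for Pck1 (adjusted p = 0.130), −0.47 for G6pc, −0.23 for Txnip, −0.15 for Cpt1a, 0.25 for Acadm and 0.04 for Pdk4, whose sign turned under some other settings. The TCA list lost its call without DKD 3, 4, 6 or 9 or enarodustat 1, 3 or 7 (adjusted p up to 0.195), with slide as a fixed block (adjusted p = 0.0515) and after normexp on the median signals (adjusted p = 0.0535). Fatty acid oxidation lost it without DKD 3 or 9 or enarodustat 7 (up to 0.113).

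Endothelial markers rose with enarodustat, with 7 risers and 11 that did not pass of 18 (9 risers adjusted over the list alone). The endothelial mean was 0.25 in 9 of 9 arrays (adjusted p = 1.35e-12, and adjusted p = 0.00193 with an estimated correlation; adjusted exact p = 0.00126). Esam, Egfl7, Cdh5 (the cadherin of endothelial junctions) and Emcn rose by 0.46, 0.44, 0.43 and 0.43. Erythroid markers had a mean of 0.63 in 8 of 9 arrays (adjusted p = 1.70e-07, and adjusted p = 0.0726 with an estimated correlation; adjusted exact p = 0.04995), with 1 riser of 10, Hbb-bt (1.11), and 7 adjusted over the list alone. Macrophage markers had a mean of 0.35 in 9 of 9 arrays with 0 of 21 past the test (adjusted p = 6.94e-08, and adjusted p = 0.201 with an estimated correlation). Lymphocyte markers had 0.33 in 9 of 9 with 0 of 16 past it (adjusted p = 0.00207, and adjusted p = 0.330 with an estimated correlation). Adjusted over the list alone, 0 macrophage and 4 lymphocyte markers rose. Mesangial and smooth muscle markers had a mean of 0.11 in 8 of 9 arrays and 1 riser of 15, Itga8 (0.45; adjusted p = 0.0268, and adjusted p = 0.292 with an estimated correlation). Intercalated cell (−0.17 in 8 of 9 arrays), podocyte (−0.14 in 6 of 9) and principal cell markers (−0.08 in 5 of 9) were called lower with 0 members past the test. The list tests gave adjusted p = 0.000661, 0.00976 and 0.0425, and adjusted p = 0.330, 0.330 and 0.610 with an estimated correlation. Medians within slides 1, 2 and 3 were 0.22, 0.28 and 0.31 for endothelium, 0.14, 1.21 and 1.37 for erythroid cells, 0.34, 0.43 and 0.29 for macrophages and 0.13, 0.46 and 0.17 for lymphocytes. Egfl7 lost its call for 19 of the arrays left out 1 at a time (all but DKD 4, 6 and 9 and enarodustat 2 and 7; adjusted p up to 0.101). Hbb-bt lost it for 17 (all but sham 1 and 3, DKD 2 and 5 and enarodustat 2, 3 and 7; up to 0.0927), and Itga8 without sham 4, DKD 2, 3, 5, 7 or 9 or enarodustat 2, 3, 4, 5, 6, 7 or 8 (up to 0.0838). The principal cell list was lost without DKD 2, 5, 6 or 9 or enarodustat 2, 3, 6, 7 or 9 (up to 0.151) with slide as a fixed block (adjusted p = 0.0685) and after normexp on the median signals (adjusted p = 0.0727), which also ended the lymphocyte call (adjusted p = 0.0837). The mesangial list was lost without DKD 4 or 9 or enarodustat 4 (up to 0.131). The podocyte list lost its call without enarodustat 9 (0.0716).

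Proliferation genes were called higher with enarodustat than in DKD as a list (mean 0.43 in 9 of 9 arrays) with 0 of 31 members past the test, also 0 adjusted over the list alone. The list test gave adjusted p = 5.38e-10, and adjusted p = 0.370 with an estimated correlation (adjusted exact p = 0.155). Interferon response genes had a mean of 0.22 in 9 of 9 arrays, with Rsad2 (0.59) and Oasl2 (0.52) rising and 20 that did not pass (9 risers adjusted over the list alone; adjusted p = 1.69e-05, and adjusted p = 0.330 with an estimated correlation). Fibrosis genes had a mean of 0.24 in 8 of 9 arrays and 0 of 33 past the test (1 riser adjusted over the list alone; adjusted p = 1.25e-07, and adjusted p = 0.330 with an estimated correlation), with slide medians of 0.42, 0.00 and 0.29. Male-biased genes (0.25 in 7 of 9 arrays, 0 of 17) and the unfolded protein response (0.13 in 7 of 9, 0 of 24) were called higher (adjusted p = 0.0171 and 0.0176, and adjusted p = 0.636 and 0.511 with an estimated correlation; adjusted exact p = 0.508 and 0.149). Slide medians were 0.50, −0.13 and 0.44 for male-biased genes, 0.77, 0.47 and 0.07 for proliferation, and 0.13, 0.22 and 0.46 for interferon. Tubular injury genes were not called (mean 0.05, adjusted p = 0.0875), and Havcr1 (0.24), Lcn2 (−0.05), Kap (0.05), Ren1 (0.04) and Slc5a2 (−0.17) did not pass. The signs of all but Slc5a2 turned under some other settings. The male-biased list lost its call without DKD 2, 7 or 9 or enarodustat 2 or 9 (adjusted p up to 0.163). The unfolded protein list lost its call without DKD 2 or 9 or enarodustat 2 (up to 0.0594). Rsad2 lost its call without DKD 1, 3, 7 or 9 or enarodustat 3, 4, 5, 6 or 8 (up to 0.0652). Oasl2 lost its call for 17 arrays (all but sham 1, 5 and 6, DKD 4, 6 and 8 and enarodustat 4; up to 0.0937).

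Between enarodustat and DKD 127 genes passed, 108 higher and 19 lower, with a median absolute change of 0.55; 61 differed at least 1.5-fold. With slide as a fixed block 177 passed, and within slides 1, 2 and 3 alone 4, 3 and 0 did by limma (1309, 1217 and 544 at an unadjusted p under 0.05). A fit of only the 2 groups compared gave 47 and no filter on dim probes 83. With slide row as a term, 20 genes passed, and 27 of the 36 calls of the naming rule ended. Mgarp, Slc16a3, Ankrd37, Tnfsf9, Rgs11, Prss12, Hk2, Pfkl and Pfkp still passed. With change and adjusted p in brackets, Prnd (1.60; 0.116), Egln3 (1.25; 0.0869), Stc1 (1.31; 0.115), Klk1b27 (−0.55; 0.255), Sntb2 (−0.43; 0.209), Zfp697 (−0.38; 0.362), Casr (−0.47; 0.12) and Baiap2 (−0.59; 0.0587) did not, nor did Ddit4 (0.91; 0.294), Aldoc (0.84; 0.0537), Rsad2 (0.69; 0.167), Oasl2 (0.55; 0.243), Esam (0.35; 0.308), Egfl7 (0.33; 0.421), Cdh5 (0.38; 0.243), Emcn (0.295; 0.37) and Itga8 (0.52; 0.208). As lists HIF targets, glycolysis and endothelial markers were still called. Markers of principal cells, intercalated cells, lymphocytes and podocytes, male-biased genes and the unfolded protein response were not (adjusted p = 0.0562, 0.299, 0.126, 0.35, 0.0957 and 0.274). Picked on these arrays, all 36 passing genes of the rule kept their sign in each slide. Against the DKD mean 34 did so in every enarodustat array. The count fell to 71 without enarodustat 8, 82 without DKD 7, 82 without enarodustat 4, 84 without enarodustat 5 and 84 without enarodustat 6, and was 11 among the arrays of the second slide row, which hold 3 DKD arrays. Of 46 lists 18 were called, 16 with slide as a fixed block, 3 with an estimated correlation, 5 by fry and 5 by the exact permutation test. The share of higher calls, 85.0%, was 69.1% in the deposited value table.

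**Figure D2:**
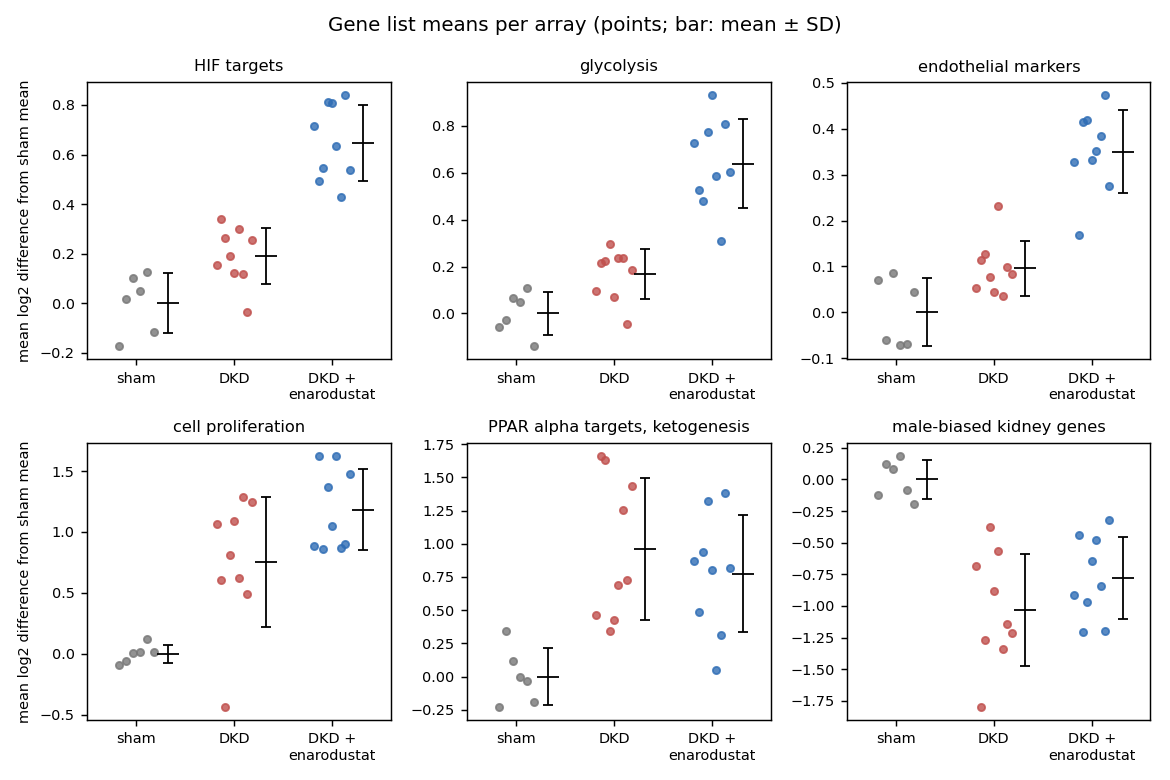
Mean log2 difference from the sham mean over the members of 6 gene lists (HIF targets, glycolysis, endothelial markers, cell proliferation, PPAR alpha and ketogenesis, and male-biased genes) in each of the 24 arrays; points are arrays and bars are the group mean ± SD. HIF targets lay at 0.19 ± 0.11 in DKD and 0.65 ± 0.15 with enarodustat.

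The enarodustat group was also set against sham to show what differs from undiseased kidneys under treatment. Mgarp, Slc16a3 and Grem1 rose the most, by 4.65 ± 0.40 (adjusted p = 4.77e-08), 4.33 ± 0.19 (adjusted p = 1.87e-13) and 4.25 ± 0.34 (adjusted p = 1.79e-08), the Mgarp probe being well above background on 3 of 6 sham arrays. Mab21l3 rose by 3.05 ± 0.37 (adjusted p = 1.02e-05). Cyp24a1, which breaks down vitamin D, rose by 2.94 ± 0.69 (adjusted p = 0.00546) and Kynu by 2.77 (adjusted p = 0.00153). Synpr changed by −4.61 ± 1.42 (adjusted p = 0.0291), Anxa13 by −3.004 (adjusted p = 0.000115), Padi3, a peptidylarginine deiminase, by −2.90 (adjusted p = 0.00158), Cyp2b10 by −2.60 (adjusted p = 0.00512) and Cyp2b9 by −2.53 (adjusted p = 0.0056). The carboxylesterase Ces1g, Adh6a and the methyltransferase Inmt changed by −2.48, −2.23 and −2.22 (adjusted p = 0.00194, 0.00629 and 0.000619). Padi3 and Ces1g were well above background on 5 of 9 enarodustat arrays and Synpr on 7 of 9. Of the genes given in every comparison, Egln3 (2.50 ± 0.23, adjusted p = 1.60e-07), Pdk1 (1.88 ± 0.38, adjusted p = 0.00167), Pdk4 (1.70 ± 0.34, adjusted p = 0.00159) and Hk2 (1.23 ± 0.37, adjusted p = 0.0247) rose. So did Pfkp (1.11 ± 0.16, adjusted p = 8.50e-05), Vegfa (0.59 ± 0.12, adjusted p = 0.00175) and Slc2a1 (0.49 ± 0.14, adjusted p = 0.0155). Differences of 0.79 for Lcn2, 0.47 for Txnip, 0.37 for Havcr1, 0.36 for Ldha, 0.28 for Pck1, −0.01 for Slc5a2, −0.06 for Cpt1a, −0.11 for Acadm, −0.25 for Kap, −0.44 for G6pc and −0.47 for Ren1 did not pass. The signs of Slc5a2, Cpt1a, Pck1 and Txnip turned under some other settings. Eda2r, a receptor of the tumour necrosis factor family above background on no sham array, was at least 2.17-fold higher (adjusted p = 4.53e-06). Within slides 1, 2 and 3 the changes were 4.49, 4.60 and 3.89 for Slc16a3 and 4.28, 4.11 and 4.37 for Grem1. Synpr lost its call without sham 1, 3 or 4 or enarodustat 3 (adjusted p up to 0.0562). Hk2 lost its call without sham 2 or 3 (up to 0.0631). Normexp on the median signals ended the calls of Hk2 (adjusted p = 0.252) and Eda2r (adjusted p = 0.207). Mgarp, Slc16a3, Grem1, Mab21l3, Kynu, Synpr, Padi3, Cyp2b9, Ces1g and Adh6a changed by 1.61, 2.80, 2.21, 1.71, 1.05, −2.99, −0.78, −1.33, −0.65 and −0.77 after normexp on the median signals, still passing.

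Against sham, proliferation genes in the enarodustat group gave 28 risers and 3 that did not pass of 31 (28 risers adjusted over the list alone). The proliferation mean was 1.18 in 9 of 9 arrays (SD 0.34; adjusted p = 6.44e-22, and adjusted p = 0.148 with an estimated correlation). Cdc20, Ccnb1 and Cenpf rose by 1.82, 1.80 and 1.68, and Bub1 was at least 3.00-fold higher (adjusted p = 0.000912). HIF targets gave 19 risers and 19 that did not pass of 38 (23 risers and 1 faller adjusted over the list alone). The HIF target mean was 0.65 in 9 of 9 arrays (adjusted p = 3.49e-12, and adjusted p = 0.0148 with an estimated correlation). Slc16a3, Ankrd37 (2.74), Egln3 and Pdk1 led the list. Glycolysis gave 10 risers and 10 that did not pass (12 risers adjusted over the list alone). The glycolysis mean was 0.64 in 9 of 9 arrays (adjusted p = 8.25e-12, and adjusted p = 0.0851 with an estimated correlation). Aldoc, Pfkl, Eno2 and Hk2 rose by 1.98, 1.58, 1.41 and 1.23. Endothelial markers gave 11 risers and 7 that did not pass (15 risers adjusted over the list alone). The endothelial mean was 0.35 in 9 of 9 arrays (adjusted p = 8.88e-09, and adjusted p = 0.0148 with an estimated correlation). Cdh5, Esam, Tek and Plvap rose by 0.64, 0.60, 0.53 and 0.50. Tubular injury genes gave 11 risers and 15 that did not pass (13 risers and 1 faller adjusted over the list alone). The tubular injury mean was 0.53 in 9 of 9 arrays (adjusted p = 1.52e-05, and adjusted p = 0.232 with an estimated correlation). Cdkn1a, Krt19, Sprr1a and Gdf15 rose by 2.12, 1.59, 1.52 and 1.18. Interferon genes gave 6 risers and 16 that did not pass (7 risers adjusted over the list alone). The interferon mean was 0.40 in 9 of 9 arrays (adjusted p = 3.50e-06, and adjusted p = 0.240 with an estimated correlation). Rsad2, Oasl2, Ifit2 and Ifi44 rose by 0.96, 0.76, 0.69 and 0.65. Principal cell markers gave 7 risers of 11, also 7 adjusted over the list alone (mean 0.43 in 9 of 9 arrays; adjusted p = 0.000465, and adjusted p = 0.246 with an estimated correlation). Aqp4, Elf5, Aqp2 and Avpr2 rose by 1.19, 0.95, 0.93 and 0.56. PPAR alpha and ketogenesis genes gave 9 risers, 2 fallers and 12 that did not pass (12 and 2 adjusted over the list alone). The PPAR alpha mean was 0.78 in 9 of 9 arrays (adjusted p = 0.00163, and adjusted p = 0.459 with an estimated correlation). Fabp1, Cyp4a10 and Acot1 rose by 2.02, 1.90 and 1.43. The fallers, singled out after their values were seen, were Bdh1 (−0.79) and Cd36 (−0.60). Slide medians for slides 1, 2 and 3 were 1.38, 1.40 and 1.1 for proliferation, 0.40, 0.54 and 0.36 for HIF targets, 0.38, 0.51 and 0.42 for glycolysis, and 0.32, 0.41 and 0.42 for endothelium. They were 0.47, 0.46 and 0.48 for injury, 0.22, 0.41 and 0.57 for interferon, 0.49, 0.32 and 0.25 for principal cells, and 0.56, 0.50 and 0.86 for PPAR alpha and ketogenesis. Aqp4 lost its call without sham 1 or 2 (adjusted p up to 0.0747). Normexp on the median signals ended the calls of Bub1 (adjusted p = 0.354) and Fabp1 (adjusted p = 0.172). Eno2, Krt19, Sprr1a, Ifit2, Ifi44, Ccnb1, Cenpf and Elf5 changed by 0.55, 0.765, 0.74, 0.28, 0.41, 0.79, 0.56 and 0.31 after normexp on the median signals, still passing.

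Cholesterol synthesis was lower than in sham also under enarodustat, with 12 fallers and 10 that did not pass (19 fallers adjusted over the list alone). The cholesterol synthesis mean was −0.46 in 9 of 9 arrays (adjusted p = 3.43e-08, and adjusted p = 0.148 with an estimated correlation). Idi1 and Insig1 changed by −1.16 and −0.72. Male-biased genes gave 10 fallers and 7 that did not pass (11 fallers adjusted over the list alone). The male-biased mean was −0.78 in 9 of 9 arrays (adjusted p = 1.45e-07, and adjusted p = 0.234 with an estimated correlation). Gusb, Cyp4a12b, Cyp4a12a and Slco1a1 changed by −1.87, −1.38, −1.35 and −1.19. The unfolded protein response gave 8 fallers (Sel1l −0.72, Sdf2l1 −0.67, Creld2 −0.66 and Edem1 −0.56 the largest) and 15 that did not pass, with Ppp1r15a rising (0.41, singled out after its value was seen). Adjusted over the list alone it gave 1 riser and 12 fallers (mean −0.25 in 9 of 9 arrays; adjusted p = 7.81e-05, and adjusted p = 0.232 with an estimated correlation). Lymphocyte markers gave 4 fallers of 16, also 4 adjusted over the list alone: Gzmb (−1.26, above background on 2 of 9 enarodustat arrays), Gzma (−1.13), Klrb1c (−0.99) and Cd3e (−0.49). The lymphocyte mean was −0.49 in 8 of 9 arrays (adjusted p = 0.00085, and adjusted p = 0.240 with an estimated correlation). Branched-chain amino acid degradation gave 5 fallers, Ivd (−0.82), Mccc1 (−0.70), Dbt (−0.43), Pcca (−0.39) and, singled out after its value was seen, Mmut (−0.28), also 5 adjusted over the list alone (mean −0.20 in 8 of 9 arrays; adjusted p = 0.00313, and adjusted p = 0.719 with an estimated correlation; adjusted exact p = 0.0887). Fibrosis genes gave 7 risers and 26 that did not pass (10 risers adjusted over the list alone). Lum, Fbn1, Lox and Thbs1 rose by 0.73, 0.73, 0.70 and 0.65, and the fibrosis mean was 0.25 in 8 of 9 arrays (adjusted p = 0.00219, and adjusted p = 0.642 with an estimated correlation). Of 15 mesangial and smooth muscle markers, Cnn1 (0.70) and Rgs5 (0.64) rose (mean 0.22 in 9 of 9 arrays; adjusted p = 0.0246, and adjusted p = 0.232 with an estimated correlation), also 2 adjusted over the list alone. Erythroid (0.08, adjusted p = 0.441) and macrophage markers (0.21, adjusted p = 0.159), oxidative phosphorylation (−0.09, adjusted p = 0.0722), the TCA cycle (−0.05, adjusted p = 0.549) and fatty acid oxidation (0.10, adjusted p = 0.423) were not called. Slide medians for slides 1, 2 and 3 were −0.46, −0.36 and −0.43 for cholesterol synthesis, −0.81, −0.79 and −0.72 for male-biased genes, and −0.32, −0.23 and −0.30 for the unfolded protein response. They were −0.50, −0.43 and −0.36 for lymphocytes, −0.21, −0.10 and −0.18 for branched-chain degradation, 0.24, 0.28 and 0.30 for fibrosis, and 0.25, 0.34 and 0.20 for mesangial markers. Slco1a1 lost its call without sham 2, 3, 4, 5 or 6 or enarodustat 1, 3, 4 or 8 (adjusted p up to 0.0769). Cd3e lost its call without sham 3, 5 or 6 or enarodustat 1, 3, 6 or 7 (up to 0.0896). Lox lost its call without sham 2, 3 or 4 or enarodustat 1 or 8 (up to 0.0885). Insig1 lost its call without sham 2 or 5 (up to 0.0708). Pcca lost its call without sham 2 or 3 (up to 0.061). The mesangial list lost its call without enarodustat 4 (0.0531). After normexp on the median signals Gzmb (adjusted p = 0.338), Lox (adjusted p = 0.198) and Lum (adjusted p = 0.283) did not pass. Klrb1c changed by −0.31 after normexp on the median signals, still passing.

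In all, 2748 genes passed between enarodustat and sham, 1550 higher and 1198 lower, with a median absolute change of 0.55, and 1252 differed at least 1.5-fold. With slide as a fixed block 3460 passed, and within slides 1, 2 and 3 alone 36, 30 and 7 did (2596, 2357 and 1483 at an unadjusted p under 0.05). Picked on these arrays, all 77 passing genes of the rule kept their sign in each slide. Against the sham mean 72 did so in every enarodustat array. Of 46 lists 15 were called, 15 with slide as a fixed block and 2 with an estimated correlation. Fry called 16 (2 calls lost) and exact permutation 16 (1 lost). The share of higher calls, 56.4%, was 44.9% after normexp on the median signals and 44.9% after scaling to the median of the tested genes. All sham arrays lay in the first slide row and all enarodustat arrays in the second, so that row and group separate only through the DKD arrays, 6 and 3 of them. With slide row as a term in the fit of all arrays 889 genes and 17 lists passed, and 44 of the 77 calls of the naming rule ended. Lost and smaller by over 1.5 times there, with change and adjusted p in brackets, were Cyp2b10 (−1.02; 0.517), Cyp2b9 (−1.15; 0.46), Pdk1 (0.905; 0.348), Cyp4a10 (1.14; 0.342), Acot1 (0.59; 0.606), Cdkn1a (1.29; 0.0923), Cyp4a12b (−0.71; 0.475), Cyp4a12a (−0.66; 0.484), Aqp4 (0.69; 0.476), Avpr2 (0.21; 0.599), Plvap (0.31; 0.211), Slc2a1 (0.31; 0.396) and Pdk4 (0.765; 0.372). Also lost, with adjusted p, were Cyp24a1 (0.118), Kynu (0.132), Synpr (0.385), Anxa13 (0.0763), Ces1g (0.0865), Adh6a (0.276), Inmt (0.0711), Fabp1 (0.182), Idi1 (0.0667), Insig1 (0.297), Mccc1 (0.0556), Dbt (0.289), Sel1l (0.076) and Sdf2l1 (0.12). The same held for Edem1 (0.227), Gdf15 (0.198), Lum (0.154), Lox (0.159), Ifit2 (0.0594), Ifi44 (0.146), Gusb (0.158), Slco1a1 (0.222), Elf5 (0.0582), Esam (0.119), Cnn1 (0.0574), Rgs5 (0.282), Gzmb (0.0565) and Klrb1c (0.259). Hk2, Cenpf, Pcca and Cd3e were larger there (2.66, 2.77, −0.74 and −0.86). The PPAR alpha and mesangial lists were not called (adjusted p = 0.346 and 0.0542).

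Whether enarodustat moved diabetic changes back was read from genes that passed both in DKD against sham and in enarodustat against DKD. Opposite directions were found for 20 genes, 7 that rose and then fell and 13 that fell and then rose, and the same direction for 15; independent lists of these sizes would share 7.66 and 7.08. The globin Hbb-bt changed by −0.95 in DKD and 1.11 with enarodustat, Acmsd by −0.69 and 0.78, Isg20, an exonuclease induced by interferon, by −0.67 and 0.69, Defb19 by −1.09 and 1.00, and Tmigd1 by −0.78 and 0.55. Zdhhc22 changed by −1.28 and 0.87, Mospd4 by −1.15 and 0.88 and Tceal1 by −0.47 and 0.47, the Mospd4 probe being well above background on 3 of 9 DKD and 7 of 9 enarodustat arrays. In the other direction Utp20 changed by 1.05 and −0.65 and Rab6b by 0.68 and −0.48. Across genes, which are not independent replicates, the changes of the comparisons correlated at −0.156; simulated unchanged groups sharing the DKD arrays gave a median of −0.447 (−0.777 to 0.047). The covariance was −0.0154 against −0.0205 in the simulation. When the DKD arrays were split so that none entered both comparisons, opposite directions were found for 0 genes and the same direction for 6 in either arrangement (1419 and 27 calls by limma with odd-numbered DKD arrays against sham, 744 and 78 with even-numbered ones). Genes called in DKD then moved with enarodustat by −0.033 and −0.144 of their diabetic change, and the mean score of those genes differed between enarodustat and the held-out DKD arrays by −0.008 and −0.095 (exact permutation, p = 0.931 and 0.257). In simulated data of independent genes a share of 0.5 of each change was undone. The slopes were then −0.443 and −0.401 and the split still found 74 and 60 opposite genes. Leaving out 1 array lowered the count of 20 to 10 without sham 4, 11 without sham 5, DKD 3 or enarodustat 8, 12 without sham 2, sham 3, DKD 7, enarodustat 2, enarodustat 6 or enarodustat 9, and 13 without enarodustat 5. With slide as a fixed block it was 35 and with cyclic loess 32, with no filter on dim probes 10, with only the 2 groups compared 2, and at an adjusted p under 0.01 it was 0. With slide row as a term it was also 0, and the calls with enarodustat ended, with change and adjusted p in brackets, for Hbb-bt (1.45; 0.116), Acmsd (0.84; 0.12), Isg20 (0.67; 0.242), Defb19 (0.96; 0.29) and Tmigd1 (0.52; 0.261). Zdhhc22 (1.09; 0.17), Mospd4 (0.925; 0.139), Tceal1 (0.48; 0.256), Utp20 (−0.78; 0.128) and Rab6b (−0.48; 0.243) lost theirs as well. Several of these genes lost their call with enarodustat when 1 array was left out: Defb19 (all but DKD 4 and enarodustat 3 and 7; adjusted p up to 0.102), Tceal1 (all but sham 5, DKD 9 and enarodustat 1; up to 0.109) and Zdhhc22 (all but DKD 2 and 7 and enarodustat 4, 6 and 7; up to 0.110). Tmigd1 did so without DKD 2, 3, 7, 8 or 9 or enarodustat 1, 2, 4, 5, 6 or 9 (up to 0.0765), and Hbb-bt and Utp20 as given above. In DKD, Hbb-bt did so as given above and Tceal1 without sham 5 (0.0525). Normexp on the median signals ended the calls of Defb19 (−0.37 and 0.30, adjusted p = 0.095 and 0.439) and Mospd4 (−0.17 and 0.069, adjusted p = 0.246 and 0.999) in both comparisons. With enarodustat it ended those of Tceal1 (0.21, adjusted p = 0.214) and Zdhhc22 (0.50, adjusted p = 0.090). Zdhhc22 and Tceal1 changed in DKD by −0.78 and −0.23 after normexp on the median signals, still passing.

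The same split was applied to the 46 gene lists, so that no DKD array entered both values of a list, with p adjusted over the lists of an arrangement. With odd-numbered DKD arrays set against sham and the others against enarodustat, glycolysis differed by 0.16 in DKD and by a further 0.46 with the drug (exact permutation p = 0.0014, adjusted 0.0322), and by 0.18 and 0.48 in the reverse arrangement (exact p = 5e-04, adjusted 0.00767). HIF targets differed by 0.18 and 0.45 (exact p = 0.0014, adjusted 0.0322) and by 0.20 and 0.46 (exact p = 5e-04, adjusted 0.00767). Endothelial markers differed by 0.07 and 0.22 (exact p = 0.0028, adjusted 0.0429) and by 0.13 and 0.28 (exact p = 5e-04, adjusted 0.00767). For these 3 lists the differences with the drug had the sign of those in DKD, and 5e-04 is the smallest p this arrangement allows. No list whose difference with the drug was opposite in sign to that in DKD passed. Lymphocyte markers differed by −0.87 and 0.29 (adjusted exact p = 0.542) and by −0.78 and 0.37 (adjusted exact p = 0.144). Erythroid markers differed by −0.59 and 0.57 (adjusted exact p = 0.540) and by −0.48 and 0.67 (adjusted exact p = 0.0689). Male-biased genes differed by −1.08 and 0.19 (adjusted exact p = 0.961) and by −0.97 and 0.30 (adjusted exact p = 0.343), and the unfolded protein response by −0.38 and 0.12 (adjusted exact p = 0.656) and by −0.37 and 0.13 (adjusted exact p = 0.270). PPAR alpha and ketogenesis genes, which rose in DKD, differed by 1.04 and −0.08 (adjusted exact p = 0.961) and by 0.85 and −0.27 (adjusted exact p = 0.593). Fatty acid oxidation differed by 0.23 and −0.05 (adjusted exact p = 0.961) and by 0.15 and −0.13 (adjusted exact p = 0.575), and cholesterol synthesis, which fell, by −0.48 and 0.04 (adjusted exact p = 0.961) and by −0.50 and 0.01 (adjusted exact p = 0.927).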

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

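Of the tests below, those of the proximal tubule share, of more blood and of the slide row for Phlda3 and Psrc1, and the choice of these genes, came only after the results they concern were seen. In 399 group tests over 133 named genes, an array lay far from the rest of its group in 30, by a gap to the nearest array that took an unusual share of the group's range; chance alone marks about 1 group in 20. The arrays with the most genes were enarodustat 5 (5), DKD 3 (4) and sham 2 (3). Each is given with that share and, where it helps, its level.

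Among sham arrays, in sham 1 the gap took 0.733 of the range for Cyp4a14, the lowest at −6.18, and 0.708 for Eda2r, the highest at −6.25. Sham 3 had the highest Aldoc (0.699) and the lowest Casr (0.694). Sham 5 had the lowest Ifit2 (0.772) and the highest Aurka (0.795). Sham 2 had the lowest Lcn2 (0.772), Sprr1a (0.757) and Fbn1 (0.626). Sham 6 had the lowest Lum (0.637) and Tmigd1 (0.629), and sham 4 the highest Thbs1 (0.634).

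Among DKD arrays, DKD 2 had the highest Creb3l3 (0.507; −0.11, nearest −2.47) and the highest Lcn2 (0.747; 0.06, nearest −1.39). DKD 3 had the highest Pklr (0.518), Aqp4 (0.587) and Pck1 (0.573) and the lowest Cenpf (0.613; −5.15, nearest −3.22). DKD 7 had the lowest Ifit2 (0.626), DKD 9 the lowest Cyp24a1 (0.517; −0.75, nearest 1.73) and DKD 4 the highest Inmt (0.498).

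Among enarodustat arrays, enarodustat 5 had the highest Gzma (0.526), Egfl7 (0.588) and Emcn (0.523) and the lowest Sntb2 (0.502) and Cenpf (0.653; −3.77, nearest −2.44). Enarodustat 6 had the highest Chac1 (0.509) and the lowest Rab6b (0.577). Enarodustat 8 had the highest Havcr1 (0.509) and enarodustat 1 the highest Lcn2 (0.551; 0.23, nearest −1.16). Enarodustat 5 also had the lowest array weight, 0.338, followed by DKD 5 (0.442) and DKD 9 (0.473).

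Probes without a gene name lie outside the comparisons of genes. Of 15047 such probes tested, 275 passed in DKD against sham (130 higher, 145 lower), 12 in enarodustat against DKD (12 higher, 0 lower) and 1095 in enarodustat against sham (839 higher, 256 lower). They were fitted as genes were, with p adjusted over these probes alone.

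Male-biased kidney genes were lower in DKD than in sham (list mean −1.031, SE 0.160, exact permutation p = 0.000599). A lower share of proximal tubule cells, which express several of these genes, would lower proximal tubule markers by at least 0.5 of that amount. They differed by −0.024 (SE 0.044), with 6 risers and 8 fallers of 33, which leaves this open. The row of the slide as the cause is argued against by the 6 sham and 6 DKD arrays of row 1, where the difference was −1.039 (exact permutation p = 0.00216). An effect of the diabetic state, of alloxan itself, which the design does not separate from diabetes, or of the position of arrays within a row stays open.

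Erythroid markers were higher with enarodustat than in DKD by 0.626 (SE 0.181, exact permutation p = 0.00469). The row of the slide is argued against by the 3 DKD and 9 enarodustat arrays of row 2, which differed by 0.801 (exact permutation p = 0.00909). More blood left in the kidney may raise other blood cells, and neutrophil markers differed by 0.17 (SE 0.094, exact permutation p = 0.0893), which leaves this open. Lymphocyte markers differed by −0.828 in DKD against sham and by 0.334 with the drug, macrophage markers by −0.132 and 0.346, and erythroid markers by −0.542 and 0.626. An effect of the drug on red cells, of vessels on retained blood or of the slide column stays open and untested.

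Phlda3 and Psrc1, targets of the tumour suppressor p53 singled out after their values were seen, were higher in DKD than in sham by a mean of 1.785 (SE 0.146). A wider rise of p53 targets is a candidate explanation: of 22 others, listed before their values were seen, 9 rose and 0 fell, and their mean was 0.197 higher in DKD (SE 0.058, exact permutation p = 0.00539). In row 1 the 2 genes differed by 1.818. Its arrays served to choose them, so this is no independent test of the row. With enarodustat the 22 genes differed from DKD by 0.021 (SE 0.065, exact permutation p = 0.740). Whether array position, alloxan or the diabetic state caused the rise was not tested.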

How the results depend on the processing

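The tests chosen after seeing the data were normexp, the single slide rows, slide row as a term and exact permutation of list means. Genes changed numbered 2058 in DKD against sham, 127 in enarodustat against DKD and 2748 in enarodustat against sham, with 20 in opposite directions and 14, 18 and 15 lists called. Under other settings 101 such counts stayed within 1.5 times and 30 did not, and 0 lists or named genes past the threshold reversed; calls ended in 305 cases for named genes and 138 for lists, and at least 1 setting ended 124 of 189 gene and 42 of 47 list calls. Leaving out 1 array gave 1471 to 2260, 71 to 128, 1967 to 3040 and 10 to 22 genes, and 11 to 17, 14 to 22 and 15 to 17 lists, and ended 36 gene and 12 list calls. Stricter thresholds lower counts by construction: an adjusted p under 0.01 gave 937, 40, 1259 and 0 genes and 9 lists in DKD against sham, and a fold of at least 1.5 gave 993, 61, 1252 and 8. With no filter on dim probes 83 genes passed with enarodustat and 10 in opposite directions. Cyclic loess gave 32 opposite genes, slide as a fixed block 35, and array weights 5119 genes in enarodustat against sham. A fit of only the 2 groups compared gave 47 and 2 opposite. In slide row 2 enarodustat against DKD gave 11, with 3 DKD arrays. Slide row as a term gave 20 genes there, 889 in enarodustat against sham and 0 opposite, and ended 11, 27 and 44 named calls. The DKD split gave 0 and 0 opposite genes. Lists called with an estimated correlation numbered 0, 3 and 2, and with enarodustat 5 by fry and 5 by exact permutation. Except for thresholds and fewer arrays, the cause was not tested. With the replicate block, on the 2 groups compared and shared numbers only, 358, 23 and 1926 genes passed, 0 in opposite directions; the same arrays without the block gave 1030, 47 and 2409. Of named calls in the 3 comparisons that fit ended 41, 25 and 12, by the block and fewer arrays together, and normexp on the median signals 10, 8 and 7. With enarodustat against DKD slide row 2 ended 29 and the fit of 2 groups 18. Same-numbered arrays correlated over 0.1 in 3 of 6, 4 of 9 and 3 of 6 pairs, and 3, 0 and 1 correlated best with their own number, so the numbers do not pair the samples. Normexp on the mean signals (column absent), leaving out saturated probes (0) and scan date (the slide) were not run.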

Other observations

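The splits below were planned, except those with sham kept or within slides, while the p53 values came after the main results. Further p53 targets that rose in DKD against sham were the apoptosis gene Pmaip1 (0.97), the death receptor gene Tnfrsf10b (0.86), the kinase gene Plk2 (0.84) and Ccng1 (0.69). Adjusted over the list alone, 11 of the 22 rose and 2 fell, Ei24 (−0.28) and Perp (−0.28). Neutrophil markers had a mean of −0.38 in DKD against sham (adjusted p = 0.0882 by camera; adjusted exact p = 0.00657), with S100a8 (−1.03) and S100a9 (−1.07) falling, and 0.17 with enarodustat (adjusted p = 0.168). Genes of the renin-angiotensin system had a mean of −0.18 in DKD (adjusted p = 0.342; adjusted exact p = 0.0387), with Ace (−1.29) and Mas1 (−1.17) falling and Agt (1.1) rising, and Ren1 at −0.51 without passing. Among macrophage markers Csf1r fell by 0.89 in DKD, and among intercalated cell markers Car2 rose by 0.95. Genes given here by name were singled out after their values were seen, except Ren1.

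Other splits of the same arrays into groups of the same sizes, 100 with the real one, asked whether chance gives as large a result. For the 2058 genes of DKD against sham 1 split, the real one, was as large, and the highest other gave 294. For the 2748 of enarodustat against sham it was 1, with 203 the highest other, so no other split of this kind reached either count. For the 20 opposite genes the splits decide nothing. Splits of all arrays mostly call 0 genes, so that opposite calls cannot arise in them (1 split as large, highest other 0). With sham kept and only the DKD and enarodustat arrays split anew, 2 splits were as large and the highest other gave 259, but only 9 of the other splits had any call for the drug, and 8 of these had opposite calls. For the 127 genes of enarodustat against DKD 3 splits were as large, a share under the level of 0.05 that does not exclude chance. The highest other gave 1789. That split took 2, 3 and 4 arrays from slides 1, 2 and 3 and points to a structure among the arrays that follows neither drug nor slide; another gave 219, with 4, 0 and 5 arrays, and with slide as a fixed block the real count was 177. For the 18 lists of enarodustat against DKD 4 splits were as large (highest other 21), a share under 0.05 that again does not exclude chance. For the 14 lists of DKD against sham 14 splits were as large (highest other 19). For the 15 of enarodustat against sham it was 29 (highest other 24), and the median of the other splits was 10 lists. These splits ignore the slide. Among 100 that kept each group's number of arrays per slide, 1, 3 and 2 gave as many genes in DKD against sham, enarodustat against DKD and enarodustat against sham (highest other 830, 2127 and 2830). No other split reached the count of DKD against sham. Other splits exceeded the real counts of both comparisons with enarodustat, so these shares, though under 0.05, do not exclude chance. The 2127 again points to a structure among the arrays. As many lists were called in 26, 7 and 35 (highest other 21, 22 and 22), so chance cannot be excluded for these counts. Single lists were tested by exact permutation.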
